A study of Mus musculus with 24 samples.

How the data were processed

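RNA of mouse subcutaneous adipose tissue was extracted with Trizol and cleaned on RNeasy columns with a DNase step, its quality was read on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion MessageAmp kit and read on Illumina BeadChip arrays, per the labels' protocols. There were 24 arrays in 8 groups of 3. Groups were taken from the sample titles, because the genotype field gives the knockout genotype for controls as well.

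The deposited series table holds 1 intensity per probe and array, on a linear scale, for 45281 probes. The scanner software, background step and normalization are not given in the sources used here. From the values, the authors quantile-normalized the intensities separately in 4 sets of 6 arrays, each a knockout group with its own controls: sorted values within a set differed by at most 0.705, 0.463, 0.189 and 0.173 intensity units in the chow C/EBPα, PPARγ, 3 day and 1 month high fat diet sets, while the sets differed from each other. No background had been subtracted. The median intensity was 151 in the chow C/EBPα set, 122 in the PPARγ set, 110 at 3 days and 116 at 1 month on high fat diet, against an estimated background of 132, 113, 103 and 108. No array repeated another at every probe. Pearson's r between arrays of a group had a median of 0.993 (0.988 to 0.994), and between arrays of different sets a median of 0.972. For arrays the number of arrays limits the precision, and the low ratio of median signal to background limits dim genes. A deposited table of signals before normalization was not used: its 96 columns of per-array values could not be matched to samples by name, and its last 6 arrays repeat the 6 before them.

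The test planned before the data were examined started from those signals and their detection p-values, so its first steps were replaced by steps that fit the table used. The background of each set and its SD were estimated from the lower side of the peak of its intensities, signals were corrected with limma's normexp model, an offset of 16 was added and log2 was taken, so fold changes of dim genes are understated. Probes brighter than background (5% false positives) in at least 3 of the 24 arrays were kept, 30881 in all. The platform annotation gave 1 gene symbol to 34885 probes and several to 18, and 10378 probes were not listed and stay unnamed. Symbols were updated through Entrez identifiers, 34807 of which were found in the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. For each of 14783 genes the probe with the highest mean log2 signal was tested. A fold against a group in which every array was at background is given as a lower bound, "at least N-fold": the bright group's mean against the lowest signal above background of the dim arrays.

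Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on the 8 group means over all 24 arrays with a shared spread, eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The comparisons were each knockout against its controls, 4 in all, and 3 differences between knockout effects. Another 3 planned comparisons, of diet, of time and of line among controls, were not tested because the sets were normalized separately. The tests, covariates, gene lists and naming rule were fixed before the data were examined. The text names Cebpa and Pparg, the 12 genes with the largest change in each direction among called genes whose 3 knockout arrays all lay on one side of the 3 controls, a choice from the up to 4 members per gene list with the smallest adjusted p, and for differences the 5 largest in each direction; a few others are named with their values. Counts of fully separated genes are given beside the 10% that chance gives for 3 against 3.

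There were 30 gene lists: adipocyte markers, textbook PPARγ targets, textbook C/EBPα targets, adipogenic transcription factors, fatty acid and triglyceride synthesis, lipolysis and lipid droplet, cholesterol synthesis, fatty acid oxidation, respiratory chain and citrate cycle, branched chain amino acid breakdown, brown and beige fat, insulin signalling and glucose use, adipokines, macrophage, inflammatory, extracellular matrix, stromal, endothelial, B and T lymphocyte, neutrophil, epithelial, skeletal muscle, red blood cell and nerve markers, immediate early genes, ER stress, cell death, cell cycle, circadian clock and sex-linked genes. Some genes are in several lists. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over 120 tests, and again with a correlation estimated from the data; 90 tests on the differences were added after seeing the data. Correlations of fold changes are across genes, over 6 pairs of comparisons.

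Alternatives covered the background step, the filter on dim probes, the probe per gene, the arrays in the fit, the replicate number as a block, array weights, the threshold and leaving out each array. Added after seeing the data were quantile normalization over all 24 arrays, muscle and lymphocyte levels as covariates, leaving out 2 arrays, precision weights per set, list tests with each array left out, the C/EBPα target list without Pparg, and precision weights and each array left out for the genes called in all 4 comparisons. The code was tested on 5 simulated data sets with 200 changed genes per comparison among a median of 13437 genes. At folds of 1.5, 2 and 4 it called 53.3%, 75.7% and 91.1% of changed genes in the chow C/EBPα set, 47.2%, 69.8% and 81.8% in the PPARγ set, 47.9%, 63.1% and 83.3% at 3 days and 45.6%, 65.1% and 83.9% at 1 month on high fat diet. Unchanged genes made up 31.6% of the calls in the chow C/EBPα set (26.6% to 37.6% over the 5 data sets), 6.16%, 3.71% and 4.82% in the other sets in the same order, and 11.7%, 9.61% and 3.71% for the differences between C/EBPα and PPARγ, between diets and between times. Of 600 simulated list tests 1 was called. Folds were preset and noise was drawn for each probe on its own. These shares are not error rates of the real counts, nor of lists where genes move together.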

Results

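Gene expression was measured in subcutaneous adipose tissue of C57BL/6J mice on 24 Illumina BeadChip arrays, which read the brightness of biotin-labelled cRNA bound to each probe. The arrays formed 8 groups of 3. C/EBPα knockout mice and their control littermates received doxycycline in chow for 3 days, in a high fat diet for 3 days, or in a high fat diet for 1 month, and PPARγ knockout mice and their controls received doxycycline in chow for 3 days. The sample titles name the knockouts Adn-C/EBPα-/- and Adn-PPARγ-/-. The mice were 10 weeks old at 3 days and 14 weeks old at 1 month. C/EBPα and PPARγ are transcription factors that drive the formation of fat cells. The series title places the question in mature adipocytes: which genes depend on each factor once the cell is formed. Whole tissue RNA also shifts with its mix of cell types. Lower adipocyte and higher macrophage lists may reflect that mix, which was not tested. The labels do not state that the 3 replicates of a group were separate animals, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Of 45281 probes, between 52.3% and 58.0% per set of 6 arrays were brighter than background, and 14783 genes were tested. Fold changes are log2, knockout minus control, ± the standard error of the limma fit, with n = 3 arrays per group, and a gene is called at an adjusted p under 0.05.

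The targeted gene was lower in each C/EBPα knockout group. The Cebpa probe ILMN_1247147 read 487 ± 52.8 (SD, n = 3) in chow controls and 235 ± 21.8 in knockouts, so that 48.2% of the signal remained. At 3 days on high fat diet the same probe read 563 ± 104 against 120 ± 13.8, leaving 21.3%, and at 1 month 836 ± 85.0 against 61.1 ± 14.9, leaving 7.30%. The RNA was of whole tissue, so the signal left does not measure how many adipocytes kept the gene. In the PPARγ knockout Cebpa fell as well, from 1162 ± 112 to 435 ± 36.7, leaving 37.5%. The 3 Pparg probes disagreed in the PPARγ knockout; adjusted p-values of single probes are over all probes tested, more than with 1 probe per gene. ILMN_1221594 fell from 282 ± 31.9 to 126 ± 26.3, a log2 fold change of -1.08 ± 0.18 (adjusted p = 7.8e-04). ILMN_1221060 rose from 5624 ± 123 to 12127 ± 859 (1.10 ± 0.12) and ILMN_1221893 from 141 ± 13.5 to 355 ± 8.88 (1.24 ± 0.15). A probe outside the deleted part of a gene does not check the deletion, and the position of these probes was not used here. In the C/EBPα knockouts on high fat diet ILMN_1221893 fell, by 1.18 ± 0.15 at 3 days and by 1.59 ± 0.15 at 1 month on the log2 scale. The other probes moved less: ILMN_1221060 was at -0.43 ± 0.12 (adjusted p = 0.0681, or 0.0451 and so called as the 1 probe of the gene) at 3 days and -0.54 ± 0.12 (adjusted p = 0.00226) at 1 month, and ILMN_1221594 at -0.34 ± 0.18 (adjusted p = 0.518) and -0.60 ± 0.18 (adjusted p = 0.0322). Pparg was the only called gene of the PPARγ comparison with probes called in both directions, and 8 genes were so in the 1 month comparison.

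**Figure D1:**
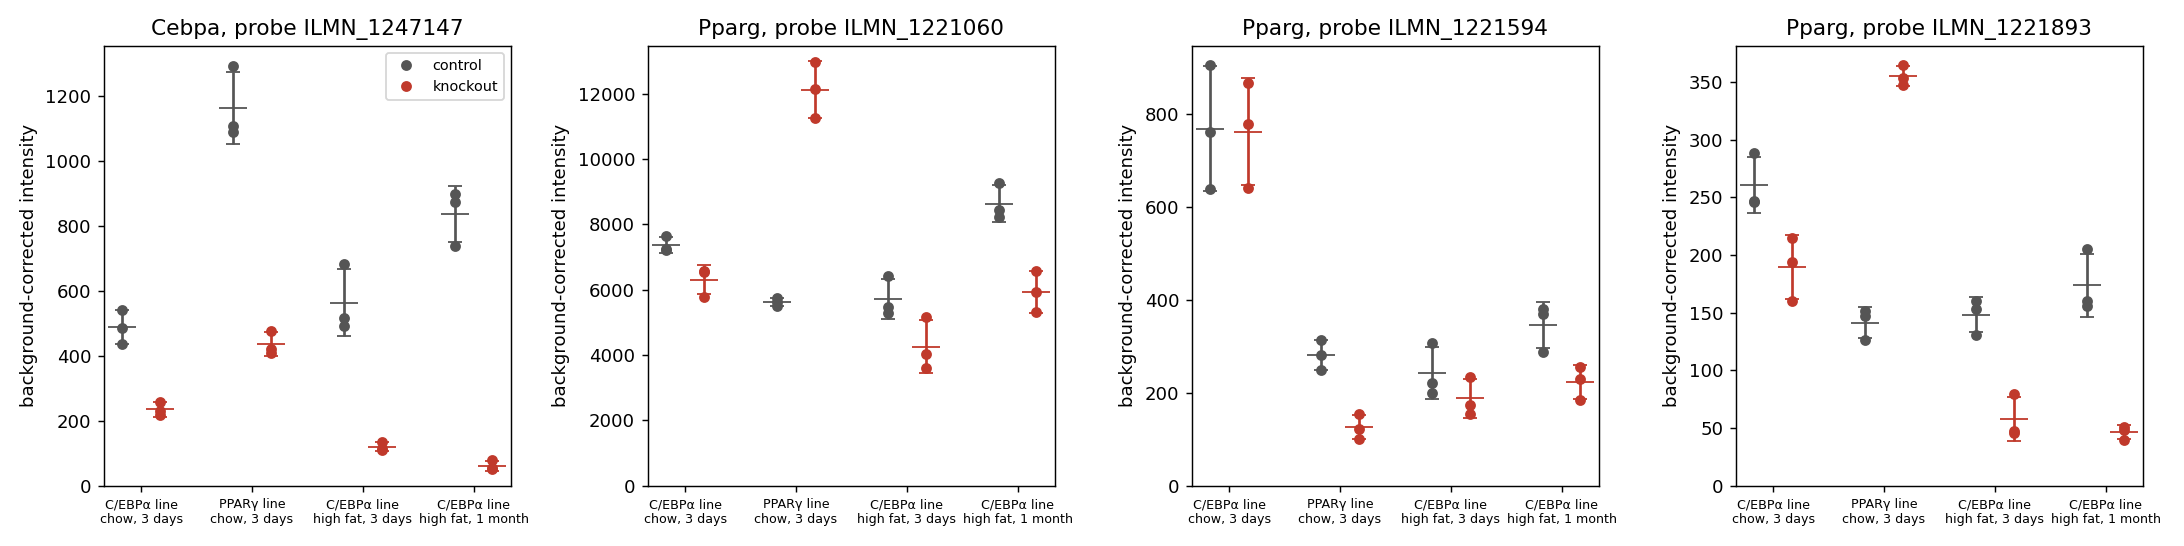
Background-corrected intensity of the Cebpa and Pparg probes per array, control against knockout, in each of the 4 comparisons, with group means and SD bars (n = 3). The Cebpa probe kept 48.2%, 37.5%, 21.3% and 7.30% of its control signal in the C/EBPα chow, PPARγ chow, C/EBPα high fat diet 3 day and 1 month knockouts.

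On chow, 3 days of C/EBPα loss went with lower mRNA of resistin, an adipokine (Retn, -0.95 ± 0.17) and of other genes. The major urinary protein genes Mup2, Mup6 and Mup20 fell by 1.81 ± 0.28, 1.73 ± 0.21 and 1.28 ± 0.19 on the log2 scale; these paralogs are so alike that a probe may not tell them apart. Fgfr1op2 (-1.53 ± 0.22, and -0.44 by a second probe), Sspn, a member of the dystrophin complex (-1.14 ± 0.18), Rassf8 (-1.13 ± 0.17), Nudt6 (-1.49 ± 0.18) Tshr, the thyrotropin receptor (-1.05 ± 0.23), and Crtc2 (-0.92 ± 0.22) also fell. Adamts17, a secreted protease, was at least 1.59-fold lower, its knockout arrays being at background. Among the genes that rose were Csrp1, which encodes a LIM domain protein of smooth muscle (3.20 ± 0.75), the cytochrome P450 gene Cyp2f2 (1.34 ± 0.28), Cpne9 (1.21 ± 0.20), the angiopoietin Angpt4 (1.19 ± 0.25), Gpx8 (1.02 ± 0.20), Itih4 (0.97 ± 0.17), Bcat1 (0.83 ± 0.16), Aldh3b2 (0.83 ± 0.15), Layn (0.79 ± 0.17) and Pianp (0.76 ± 0.17). The transcript 4933402J07Rik was at least 1.42-fold higher, and H2-M11 was higher as well. The probes of Cpne9 and Pianp were above background in 1 of 3 control arrays and that of Csrp1 in 2, and in the knockouts that of Mup20 in 1 and that of Crtc2 in 2.

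In all, limma called 158 genes on chow, 79 higher and 79 lower, of which 5 and 9 changed at least 2-fold. In 17.8% of genes all 3 knockout arrays lay on one side of all 3 controls, where chance gives 10%. This count may carry more error than the others. Dim probes of this set varied more between arrays (median SD 0.225 among the dimmest genes, against 0.136 to 0.149 in the other sets). In simulated data 31.6% of calls in this set were unchanged genes. Without background correction limma called 322 genes, 124 of them among the 158, and 267 probes were called when each was tested. Precision weights per set, chosen after seeing the data, left 67 calls, 65 of them among the 158, array weights left 54, and a fit on the 6 chow arrays alone called 1 gene, Csrp1 (adjusted p = 0.0199). With precision weights Csrp1, Angpt4, 4933402J07Rik, Layn, Pianp, Crtc2 and Tshr were no longer called among the genes named above. The shared spread of Csrp1 takes in other groups, among them the 1 month knockouts at 4.34, 8.90 and 9.51 (log2). Its standard error was 0.75 in the main fit and 0.24 in the fit on the chow arrays alone. Leaving out 1 array also ended calls. That of Csrp1 was lost whichever chow array was left out (highest adjusted p = 0.102, without control replicate 2). Cyp2f2 reached 0.0832 without knockout replicate 3, Angpt4 0.0909 without control replicate 1, Gpx8 0.0561 without knockout replicate 2, Tshr 0.111 without knockout replicate 3, Layn and Crtc2 0.0777 and 0.149 without control replicate 1, Pianp 0.114 without control replicate 2 and Bcat1 0.0616 without control replicate 3.

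Few members of the fixed gene lists changed on chow. Of the adipocyte markers, 1 of 14 fell (1 adjusted over the list alone). The adipocyte list had a median log2 fold change of -0.06 (camera adjusted p = 0.0197, adjusted p = 0.292 with an estimated correlation). Retn was the member called. Retn was also the single called member of the textbook C/EBPα targets (1 of 13, 1 adjusted over the list alone). The C/EBPα target list had a median log2 fold change of -0.16 (camera adjusted p = 0.0102, adjusted p = 0.215 with an estimated correlation). The called member of the adipokines was Retn too (1 of 18, 2 adjusted over the list alone; camera adjusted p = 0.612). Of the extracellular matrix genes 2 of 31 rose (4 adjusted over the list alone). The matrix list had a median log2 fold change of 0.17 (camera adjusted p = 3.4e-04, adjusted p = 0.351 with an estimated correlation). Those called were Col6a1 (0.41 ± 0.09) and Postn (0.45 ± 0.10). Col6a1 was not called without control replicate 1 (adjusted p = 0.113) nor Postn without control replicate 3 (0.116) or with precision weights. Macrophage markers were called higher as a list with 0 of 25 members past the test (1 adjusted over the list alone). The macrophage list had a median log2 fold change of 0.20 (camera adjusted p = 0.0120, adjusted p = 0.595 with an estimated correlation). B and T lymphocyte markers were called lower without a called member (0 of 14, 0 adjusted over the list alone). Relative to the mean of the controls, they stood at -0.56, 0.36 and 0.20 (log2) in control replicates 1, 2 and 3. In the knockouts they stood at -0.48, -0.44 and -0.88, so the groups overlapped. The lymphocyte list had a median log2 fold change of -0.63 (camera adjusted p = 0.00141, adjusted p = 0.503 with an estimated correlation). Cholesterol synthesis genes were called lower in the same way (0 of 18, 0 adjusted over the list alone). The cholesterol list had a median log2 fold change of -0.12 (camera adjusted p = 0.0453, adjusted p = 0.640 with an estimated correlation). The single called members of other lists were Pnpla3, a lipid droplet protein (-0.88 ± 0.21, not called without knockout replicate 3, adjusted p = 0.148), the stress factor Ddit3 (0.45 ± 0.09, 0.0818 without knockout replicate 1), S100b (0.51 ± 0.10, 0.0639 without knockout replicate 2) and the endothelial factor Erg (at least 1.16-fold lower, its knockout arrays being at background, 0.130 without control replicate 1). S100b and Erg were not called with precision weights either. Lists for PPARγ targets, fatty acid synthesis, lipolysis, respiratory chain and brown fat were not called. Leaving out 1 array ended list calls too: that of cholesterol synthesis without control replicate 1 or knockout replicate 3 (camera adjusted p = 0.435 and 0.426), of adipocyte markers without control replicate 3 or knockout replicate 1 (0.0915 and 0.0900), of C/EBPα targets without control replicate 3 (0.0639) and of macrophage markers without control replicate 1 (0.0530).

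In the PPARγ knockout at 3 days on chow, Slc2a4 and Rprml were among the genes with the largest falls. The insulin-regulated glucose transporter Slc2a4 fell by 1.42 ± 0.15 on the log2 scale, Dgat1, which makes triglyceride, by 1.38 ± 0.12, the sterol regulator Insig1 by 1.43 ± 0.21, the mitochondrial dicarboxylate carrier Slc25a10 by 1.40 ± 0.16 and the acyl-CoA synthetase gene Acsm5 by 1.72 ± 0.18. Rprml (-2.18 ± 0.38), the cadherin Celsr2 (-1.89 ± 0.19), the imprinted gene Nnat (-1.68 ± 0.26), 2010016I18Rik (-1.56 ± 0.26) Aldh3b2 (-1.40 ± 0.15), Cebpa (-1.38 ± 0.14) and Mfng (-1.36 ± 0.15) fell too. The secreted proteins Adamtsl2 and Angptl7 rose by 4.61 ± 0.30 and 4.37 ± 0.30 (Adamtsl2 was above background in only 1 of 3 control arrays, so the size of its rise is uncertain), the cytochrome P450 genes Cyp4f14 and Cyp2f2 by 3.13 ± 0.20 and 2.36 ± 0.28, the acute phase protein Saa3 by 3.11 ± 0.27 and the neutrophil protease Prtn3 by 2.81 ± 0.21. Angpt4 was at least 5.59-fold higher, its control arrays being at background, and Mup3 (2.58 ± 0.23) and Mup5 (2.24 ± 0.32), uncertain paralogs, Azgp1 (2.17 ± 0.29), Slc25a30 (2.34 ± 0.14) and the lysolipid transporter Mfsd2a (2.27 ± 0.21) rose.

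Limma called 1363 genes in the PPARγ knockout, 680 higher and 683 lower, 57 and 51 of them at least 2-fold, and the groups were fully separated in 29.7% of genes against 10% by chance. The count rested in part on single arrays: it was 670 without control replicate 2, 735 without knockout replicate 2 and 852 without control replicate 1. Precision weights called 2073 genes. In simulated data 6.16% of the genes called in this set were unchanged.

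Of the fatty acid and triglyceride synthesis genes, 15 of 23 fell and 0 rose in the PPARγ knockout (20 lower adjusted over the list alone). The lipid synthesis list had a median log2 fold change of -0.74 (camera adjusted p = 6.5e-19, adjusted p = 0.0439 with an estimated correlation). Examples were Srebf1, the factor that drives the pathway (-1.18 ± 0.15), the citrate carrier Slc25a1 (-1.32 ± 0.17) and Gpd1 (-1.25 ± 0.17). Adipocyte markers fell in 9 of 14 (11 adjusted over the list alone). The adipocyte list had a median log2 fold change of -0.62 (camera adjusted p = 2.9e-11, adjusted p = 0.0110 with an estimated correlation). Retn was at -1.25 ± 0.17, Cidec, a lipid droplet protein, at -0.85 ± 0.13 and Nrg4 at -0.78 ± 0.10. Of the textbook PPARγ targets 11 of 20 fell and 2 rose (13 and 3 adjusted over the list alone). The PPARγ target list had a median log2 fold change of -0.55 (camera adjusted p = 8.4e-08, adjusted p = 0.0439 with an estimated correlation). Examples were Agpat2 (-0.74 ± 0.10), the glycerol channel Aqp7 (-0.65 ± 0.09) and Pex11a (-0.57 ± 0.09). Lipolysis and lipid droplet genes fell in 7 of 23 and rose in 1 (11 and 1 adjusted over the list alone). The lipolysis list had a median log2 fold change of -0.28 (camera adjusted p = 3.7e-07, adjusted p = 0.0439 with an estimated correlation). Lipe, hormone-sensitive lipase, was at -1.26 ± 0.11 and Plin1 at -0.61 ± 0.10. Some genes stood in more than 1 of these lists. Cholesterol synthesis genes fell in 9 of 18 (13 adjusted over the list alone). The cholesterol list had a median log2 fold change of -0.51 (camera adjusted p = 5.9e-09, adjusted p = 0.151 with an estimated correlation). Examples were Lss (-0.74 ± 0.15) and Nsdhl (-0.70 ± 0.15). Textbook C/EBPα targets were not called as a list, with 4 of 13 lower and 2 higher (5 and 3 adjusted over the list alone; camera adjusted p = 0.0555). Of the 2 higher, 1 was Pparg, the targeted gene, read by ILMN_1221060. Without Pparg, a test chosen after seeing the data, 4 of 12 were lower and 1 higher, and the list was called lower (median log2 fold change -0.20, camera adjusted p = 0.00325, adjusted p = 0.146 with an estimated correlation).

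Camera with a preset correlation called several mitochondrial and metabolic lists lower in the PPARγ knockout, and none of those that follow with an estimated correlation. Of the respiratory chain and citrate cycle genes 11 of 27 fell (16 adjusted over the list alone). The respiratory list had a median log2 fold change of -0.31 (camera adjusted p = 2.3e-11, adjusted p = 0.151 with an estimated correlation). Examples were Dlat (-0.83 ± 0.13) and Pdha1 (-0.57 ± 0.13) of the pyruvate dehydrogenase complex. Branched chain amino acid breakdown genes fell in 5 of 18 (7 adjusted over the list alone). The branched chain list had a median log2 fold change of -0.19 (camera adjusted p = 8.2e-06, adjusted p = 0.156 with an estimated correlation). Bcat2, the first enzyme of the pathway, was at -0.85 ± 0.14 and Mccc2 at -0.80 ± 0.16. Fatty acid oxidation genes fell in 3 of 20 (5 adjusted over the list alone). The fatty acid oxidation list had a median log2 fold change of -0.22 (camera adjusted p = 9.5e-04, adjusted p = 0.454 with an estimated correlation). The members called were Eci1 (-0.47 ± 0.12), Etfb (-0.36 ± 0.10) and Acot2 (-0.47 ± 0.14), none of which was called without control replicate 2 (adjusted p = 0.115, 0.118 and 0.192). Brown and beige fat genes fell in 4 of 18 (6 adjusted over the list alone). The brown fat list had a median log2 fold change of -0.24 (camera adjusted p = 0.00194, adjusted p = 0.446 with an estimated correlation). Examples were Prdm16 (-0.47 ± 0.09) and the potassium channel Kcnk3 (-0.90 ± 0.19). Insulin signalling and glucose genes fell in 6 of 26 and rose in 1 (9 and 1 adjusted over the list alone). The insulin signalling list had a median log2 fold change of -0.21 (camera adjusted p = 3.0e-04, adjusted p = 0.0965 with an estimated correlation). Pyruvate carboxylase Pcx was at -1.11 ± 0.12, glycogen synthase Gys1 at -1.18 ± 0.16 and Akt2 at -0.83 ± 0.13. The brown fat list was not called without control replicate 2 (camera adjusted p = 0.0824). Relative to the mean of the controls, it stood at -0.05, 0.34 and -0.30 (log2) in control replicates 1, 2 and 3. In the knockouts it stood at -0.09, -0.46 and -0.26, so the groups overlapped.

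Macrophage markers rose in 9 of 25 and fell in 0 in the PPARγ knockout (15 higher adjusted over the list alone). The macrophage list had a median log2 fold change of 0.48 (camera adjusted p = 9.6e-10, adjusted p = 0.151 with an estimated correlation). The complement gene C1qb was at 0.54 ± 0.13. Inflammatory signals rose in 7 of 27 (12 adjusted over the list alone). The inflammatory list had a median log2 fold change of 0.42 (camera adjusted p = 4.6e-07, adjusted p = 0.151 with an estimated correlation). It was led by Saa3 and by lipocalin-2, Lcn2 (2.13 ± 0.22). Matrix genes rose in 7 of 31 (16 adjusted over the list alone). The matrix list had a median log2 fold change of 0.29 (camera adjusted p = 1.8e-08, adjusted p = 0.151 with an estimated correlation). Examples were the crosslinking enzyme Lox (1.11 ± 0.13), the inhibitor Timp1 (1.19 ± 0.25) and biglycan, Bgn (1.05 ± 0.12). Cell cycle genes rose in 7 of 18 (13 adjusted over the list alone). The cell cycle list had a median log2 fold change of 0.49 (camera adjusted p = 4.5e-07, adjusted p = 0.201 with an estimated correlation). Birc5 was at 1.11 ± 0.23 and Mcm5 at 0.87 ± 0.16. Immediate early genes rose in 5 of 15 (5 adjusted over the list alone). The immediate early list had a median log2 fold change of 0.45 (camera adjusted p = 2.3e-04, adjusted p = 0.156 with an estimated correlation). Junb was at 1.20 ± 0.23 and Jun at 0.59 ± 0.11. ER stress and amino acid response genes rose in 4 of 20 and fell in 1 (6 and 2 adjusted over the list alone). The ER stress list had a median log2 fold change of 0.21 (camera adjusted p = 0.00679, adjusted p = 0.0462 with an estimated correlation). Trib3 was at 0.90 ± 0.15 and Sesn2 at 0.88 ± 0.12. Stromal markers were called higher as a list with 3 of 20 members called (7 adjusted over the list alone). The stromal list had a median log2 fold change of 0.24 (camera adjusted p = 0.00290, adjusted p = 0.292 with an estimated correlation). Those called were Dpp4 (0.47 ± 0.12), Gsn (0.53 ± 0.15) and Thy1 (0.54 ± 0.16), and each lost its call when 1 array was left out (adjusted p = 0.0788 without knockout replicate 1, 0.158 without control replicate 1 and 0.180 without knockout replicate 2).

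At 3 days on high fat diet Mc2r and Retn were among the genes with the largest falls in the C/EBPα knockout. Cebpa itself fell by 2.08 ± 0.14 on the log2 scale, the corticotropin receptor Mc2r by 1.54 ± 0.25, the sulfate transporter Slc13a4 by 1.65 ± 0.22, Retn by 1.38 ± 0.17, the acute phase gene Hp by 1.29 ± 0.19 and the pantetheinase gene Vnn3 by 1.44 ± 0.22. Cyp2f2 rose by 3.02 ± 0.28, Prtn3 by 1.99 ± 0.21, the matrix protein Comp by 1.81 ± 0.23, Angpt4 by 1.63 ± 0.25, Itih4 by 1.55 ± 0.17 and Cebpg, another C/EBP family member, by 1.37 ± 0.14 (0.66 by a second probe). Mup2 (-1.36 ± 0.28) and Mup6 (-1.31 ± 0.21) fell again, and Mup2 was not called without control replicate 2 (adjusted p = 0.0525). Cdsn (-1.55 ± 0.23), Tex36 (-1.39 ± 0.18), Fam110c (-1.31 ± 0.28) and Chst1 (-1.27 ± 0.16) fell too, and Ccn1 (1.36 ± 0.32), Mycl (1.18 ± 0.30), Cyp2e1 (1.10 ± 0.21) and Resf1 (1.04 ± 0.17) rose. Of these Ccn1, Mycl and Fam110c were not called without control replicate 1, control replicate 2 and knockout replicate 3 in turn (adjusted p = 0.117, 0.165 and 0.0921). Tex36 and Fam110c were above background in 2 of 3 knockout arrays.

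Limma called 335 genes, 114 higher and 221 lower, 13 and 34 of them at least 2-fold, with 18.3% of genes fully separated against 10% by chance. The count fell to 170 without knockout replicate 3, 186 without control replicate 3, 209 without control replicate 2 and 217 without knockout replicate 1, and to 77 in a fit on these 6 arrays alone. Array weights called 599 genes. Markers of other tissue varied between arrays of this set: relative to the mean of the controls, skeletal muscle markers stood at 2.23 (log2) in control replicate 3 and lymphocyte markers at 1.81 in knockout replicate 3. Leaving out both arrays, an alternative chosen after seeing the data, gave 118 genes.

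Adipocyte markers fell in 4 of 14 at 3 days on high fat diet (10 adjusted over the list alone). The adipocyte list had a median log2 fold change of -0.31 (camera adjusted p = 7.7e-10, adjusted p = 0.0142 with an estimated correlation). The activin receptor Acvr1c was at -1.07 ± 0.14 beside Retn. Textbook PPARγ targets fell in 5 of 20 (13 adjusted over the list alone). The PPARγ target list had a median log2 fold change of -0.32 (camera adjusted p = 4.2e-07, adjusted p = 0.0439 with an estimated correlation). The fatty acid binding protein Fabp5 was at -1.15 ± 0.20 and Pex11a at -0.46 ± 0.09. Textbook C/EBPα targets fell in 3 of 13 (7 adjusted over the list alone). The C/EBPα target list had a median log2 fold change of -0.16 (camera adjusted p = 5.0e-06, adjusted p = 0.0461 with an estimated correlation). The members called were Retn, Adipoq (-0.41 ± 0.10) and Pparg (-0.43 ± 0.11), of which Adipoq was not called without control replicate 2 (adjusted p = 0.147) and Pparg without knockout replicate 3 (0.268). Fatty acid and triglyceride synthesis genes fell in 5 of 23 (10 adjusted over the list alone). The lipid synthesis list had a median log2 fold change of -0.34 (camera adjusted p = 1.5e-10, adjusted p = 0.151 with an estimated correlation). Gpat3 was at -1.01 ± 0.14 and Dgat1 at -0.72 ± 0.12. Cholesterol synthesis genes fell in 3 of 18 (10 adjusted over the list alone). The cholesterol list had a median log2 fold change of -0.41 (camera adjusted p = 7.0e-09, adjusted p = 0.151 with an estimated correlation). Pmvk was at -0.78 ± 0.13. Lipolysis genes fell in 3 of 23 and rose in 1 (9 and 2 adjusted over the list alone). The lipolysis list had a median log2 fold change of -0.17 (camera adjusted p = 0.00141, adjusted p = 0.151 with an estimated correlation). Abhd5, the activator of adipose triglyceride lipase, was at -0.71 ± 0.14 and Hilpda, a lipase inhibitor, at 0.88 ± 0.13. Adipokines fell in 5 of 18 and rose in 2 (7 and 2 adjusted over the list alone). The adipokine list had a median log2 fold change of -0.12 (camera adjusted p = 0.0190, adjusted p = 0.151 with an estimated correlation). Retn and Hp were among those that fell, with Lcn2 at -1.22 ± 0.22. The adipokine list was not called without control replicate 2 or knockout replicate 3 (camera adjusted p = 0.0536 and 0.0652).

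Immediate early genes rose in 3 of 15 at 3 days on high fat diet (6 adjusted over the list alone). The immediate early list had a median log2 fold change of 0.29 (camera adjusted p = 0.00353, adjusted p = 0.292 with an estimated correlation). The members called were Junb (1.12 ± 0.23), Egr1 (1.04 ± 0.27) and Zfp36 (0.53 ± 0.14). None of them was called without knockout replicate 3 (adjusted p = 0.0684, 0.261 and 0.249). Macrophage markers were called higher as a list with 1 of 25 members called, Cd14 at 0.58 ± 0.11 (1 adjusted over the list alone). The macrophage list had a median log2 fold change of 0.23 (camera adjusted p = 1.0e-04, adjusted p = 0.398 with an estimated correlation). Stromal markers were called higher with 2 of 20 (5 higher and 1 lower adjusted over the list alone). The stromal list had a median log2 fold change of 0.13 (camera adjusted p = 0.00823, adjusted p = 0.351 with an estimated correlation). Both called members, Gsn (0.75 ± 0.15) and Sfrp1 (0.38 ± 0.10), lost the call without control replicate 3 (adjusted p = 0.0583 and 0.214), and Sfrp1 with precision weights. Lymphocyte markers were called higher with 0 of 14 members called (0 adjusted over the list alone). The call rested on knockout replicate 3: relative to the mean of the controls, the list stood at -0.04, -0.23 and 1.81 (log2) in knockout replicates 1, 2 and 3. Without that array the list test turned to lower without a call (camera adjusted p = 0.375). The lymphocyte list had a median log2 fold change of 0.54 (camera adjusted p = 0.0168, adjusted p = 0.610 with an estimated correlation). Cell cycle genes were called higher with 0 of 18 (0 adjusted over the list alone). The cell cycle list had a median log2 fold change of 0.34 (camera adjusted p = 0.00272, adjusted p = 0.480 with an estimated correlation). Endothelial markers were called lower with 0 of 16 (0 adjusted over the list alone). The endothelial list had a median log2 fold change of -0.08 (camera adjusted p = 0.0297, adjusted p = 0.420 with an estimated correlation). Insulin signalling genes were called lower with Akt2 (-0.64 ± 0.13) the called member of 26 (4 adjusted over the list alone). The insulin signalling list had a median log2 fold change of -0.19 (camera adjusted p = 0.00267, adjusted p = 0.151 with an estimated correlation). Akt2 was not called without knockout replicate 3 (adjusted p = 0.0610). Branched chain amino acid genes were called lower with 0 of 18 (0 adjusted over the list alone). The branched chain list had a median log2 fold change of -0.10 (camera adjusted p = 0.0453, adjusted p = 0.566 with an estimated correlation). Other list calls ended when 1 array was left out. Without control replicate 3 these were macrophage (camera adjusted p = 0.0758), stromal (0.140) and branched chain genes (0.125), and without control replicate 2 endothelial (0.0729) and lymphocyte markers (0.0739). Without knockout replicate 3 they were endothelial (0.339) and cell cycle genes (0.325), and without knockout replicate 1 stromal (0.0557) and branched chain genes (0.159). The branched chain list was not called without control replicate 1 either (0.108).

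After 1 month on high fat diet Serpina1b and Angpt4 were among the genes with the largest changes in the C/EBPα knockout. The serine protease inhibitor genes Serpina1b (-4.91 ± 0.67) and Serpina1d (-4.25 ± 0.59) fell; a probe may not tell these close paralogs apart. Slc13a4 (-3.80 ± 0.22), Cebpa (-3.48 ± 0.14) and Mest, an imprinted gene that marks expanding fat (-3.40 ± 0.40), fell as well. So did Mc2r (-3.18 ± 0.25), the GABA transporter Slc6a13 (-3.14 ± 0.26) and Igfals, which stabilises circulating IGF (-2.74 ± 0.18). Retn was at least 6.29-fold lower, with the knockout arrays at background. Angpt4 rose by 4.60 ± 0.25, Cyp2f2 by 3.81 ± 0.28 and Itih4 by 2.92 ± 0.17. The muscle-type fatty acid binding protein Fabp3 rose by 2.61 ± 0.34 and Hsd11b2, which inactivates glucocorticoids, by 2.12 ± 0.11. Retnlg rose by 1.95 ± 0.24 and the activin antagonist follistatin, Fst, by 1.75 ± 0.13. Fam110c (-3.21 ± 0.28), Vnn3 (-3.18 ± 0.22) and Crtac1 (-3.03 ± 0.23) fell too, and Mmd2 (2.04 ± 0.30), Comp (2.01 ± 0.23), Hal (1.94 ± 0.59), Thbs2 (1.73 ± 0.12) and Adamtsl2 (1.66 ± 0.30) rose, Hal without a call when control replicate 1 was left out (adjusted p = 0.133). The probes of Angpt4, Hsd11b2, Hal and Adamtsl2 were above background in 2 of 3 control arrays, and those of Serpina1d, Mc2r and Fam110c in 2 of 3 knockout arrays. The sizes of these changes are uncertain for that reason.

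Limma called 2620 genes, 1372 higher and 1248 lower, 100 and 209 of them at least 2-fold, with 33.5% of genes fully separated against 10% by chance. Testing every probe on its own called 3964 probes. In simulated data 4.82% of the genes called in this set were unchanged.

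Macrophage markers rose in 20 of 25 and fell in 0 at 1 month (21 higher adjusted over the list alone). The macrophage list had a median log2 fold change of 0.72 (camera adjusted p = 1.1e-12, adjusted p = 0.141 with an estimated correlation). The mannose receptor Mrc1 was at 0.97 ± 0.10, Cd14 at 0.96 ± 0.11 and C1qa at 1.05 ± 0.13. Inflammatory signals rose in 10 of 27 and fell in 1 (13 and 1 adjusted over the list alone). The inflammatory list had a median log2 fold change of 0.45 (camera adjusted p = 3.1e-05, adjusted p = 0.169 with an estimated correlation). The chemokine Ccl8 was at 1.61 ± 0.22 and the adhesion molecule Vcam1 at 1.13 ± 0.15. Stromal markers rose in 10 of 20 and fell in 3 (11 and 3 adjusted over the list alone). The stromal list had a median log2 fold change of 0.38 (camera adjusted p = 0.00975, adjusted p = 0.360 with an estimated correlation). Gsn was at 1.32 ± 0.15 and Sfrp1 at 0.90 ± 0.10 against Sfrp5 at -2.18 ± 0.25 and Mest. Matrix genes rose in 13 of 31 and fell in 5 (16 and 5 adjusted over the list alone). The matrix list had a median log2 fold change of 0.22 (camera adjusted p = 0.0136, adjusted p = 0.529 with an estimated correlation). Lumican, Lum, was at 0.83 ± 0.09 and Mmp2 at 0.62 ± 0.09 against the basement membrane collagen Col4a1 at -0.67 ± 0.11 and the contractile actin Acta2 at -0.78 ± 0.10. Endothelial markers fell in 10 of 16 and rose in 0 (11 lower adjusted over the list alone). The endothelial list had a median log2 fold change of -0.35 (camera adjusted p = 2.5e-04, adjusted p = 0.151 with an estimated correlation). Robo4 was at -0.67 ± 0.10, Sox18 at -0.69 ± 0.14 and Tie1 at -0.65 ± 0.14. Cell cycle genes rose in 3 of 18 (4 adjusted over the list alone). The cell cycle list had a median log2 fold change of 0.31 (camera adjusted p = 0.00958, adjusted p = 0.551 with an estimated correlation). Cenpa was at 0.81 ± 0.15 and Ccnd1 at 0.54 ± 0.13. The cell cycle list was not called without knockout replicate 2 (camera adjusted p = 0.102).

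Adipocyte markers fell in 12 of 14 at 1 month (12 adjusted over the list alone). The adipocyte list had a median log2 fold change of -0.72 (camera adjusted p = 4.2e-11, adjusted p = 0.0110 with an estimated correlation). Acvr1c was at -1.63 ± 0.14, Cidec at -0.97 ± 0.13 and Plin1 at -0.75 ± 0.10. Textbook PPARγ targets fell in 13 of 20 and rose in 2 (13 and 2 adjusted over the list alone). The PPARγ target list had a median log2 fold change of -0.59 (camera adjusted p = 1.6e-06, adjusted p = 0.0462 with an estimated correlation). Textbook C/EBPα targets fell in 8 of 13 (8 adjusted over the list alone). The C/EBPα target list had a median log2 fold change of -0.57 (camera adjusted p = 3.0e-06, adjusted p = 0.0439 with an estimated correlation). Leptin, Lep, was at -0.95 ± 0.18, Adipoq at -0.68 ± 0.10 and the insulin receptor Insr at -0.63 ± 0.12. Fatty acid and triglyceride synthesis genes fell in 11 of 23 (11 lower and 1 higher adjusted over the list alone). The lipid synthesis list had a median log2 fold change of -0.44 (camera adjusted p = 7.0e-09, adjusted p = 0.151 with an estimated correlation). Pnpla3 was at -1.78 ± 0.21, Gpat3 at -1.68 ± 0.14 and the acetate-activating enzyme Acss2 at -1.38 ± 0.15. Lipolysis genes fell in 13 of 23 and rose in 2 (13 and 3 adjusted over the list alone). The lipolysis list had a median log2 fold change of -0.41 (camera adjusted p = 1.5e-04, adjusted p = 0.141 with an estimated correlation). Mgll, which completes triglyceride breakdown, was at -0.90 ± 0.10 and Plin4 at -0.84 ± 0.09. Cholesterol synthesis genes fell in 14 of 18 (15 adjusted over the list alone). The cholesterol list had a median log2 fold change of -0.63 (camera adjusted p = 6.8e-09, adjusted p = 0.151 with an estimated correlation). Sc5d was at -1.22 ± 0.16. Insulin signalling genes fell in 8 of 26 and rose in 1 (9 and 1 adjusted over the list alone). The insulin signalling list had a median log2 fold change of -0.20 (camera adjusted p = 0.00267, adjusted p = 0.151 with an estimated correlation). Akt2 was at -1.47 ± 0.13. Branched chain amino acid genes fell in 8 of 18 (9 adjusted over the list alone). The branched chain list had a median log2 fold change of -0.30 (camera adjusted p = 2.5e-04, adjusted p = 0.270 with an estimated correlation). Bcat2 was at -1.12 ± 0.14. Adipokines fell in 9 of 18 and rose in 3 (9 and 3 adjusted over the list alone). The adipokine list had a median log2 fold change of -0.33 (camera adjusted p = 0.0152, adjusted p = 0.151 with an estimated correlation). Orm1 was at -2.73 ± 0.13 and Hp at -2.11 ± 0.19. Brown and beige fat genes were called higher as a list: 5 of 18 rose and 1 fell (6 and 1 adjusted over the list alone). The brown fat list had a median log2 fold change of 0.29 (camera adjusted p = 0.00823, adjusted p = 0.529 with an estimated correlation). The members that rose included Fabp3, Cidea, a lipid droplet protein (1.04 ± 0.17), and the cytochrome oxidase subunit Cox7a1 (1.19 ± 0.20), while Ucp1, the uncoupling protein that defines brown fat, was at 0.70 ± 0.38 (adjusted p = 0.243). The brown fat list was not called without knockout replicate 1 (camera adjusted p = 0.0700).

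**Figure D2:**
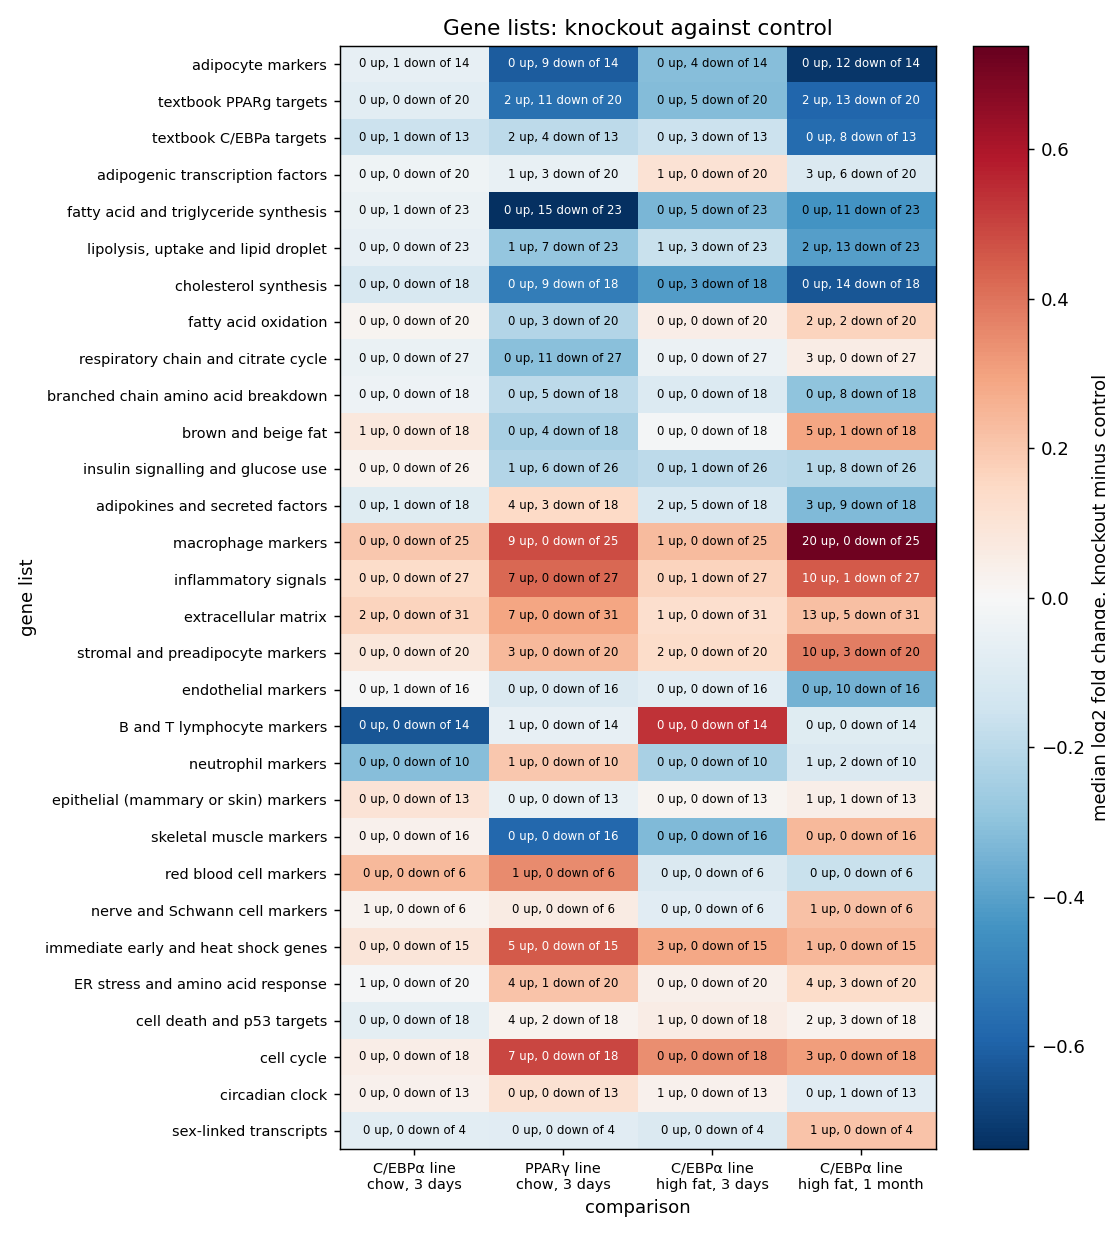
Each of the 30 gene lists (vertical axis) in the 4 knockout comparisons (horizontal axis), coloured by the list's median log2 fold change, knockout minus control, with the number of members called higher and lower among those tested. Adipocyte markers ran from -0.06 on chow to -0.72 at 1 month in the C/EBPα knockouts, and macrophage markers reached 0.72 at 1 month.

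Of the 30 lists, camera with a preset correlation called 7 in the C/EBPα knockout on chow, 18 in the PPARγ knockout, 15 at 3 days and 16 at 1 month on high fat diet. Of these, 2, 16, 8 and 14 were called whichever array of the set was left out. With a correlation estimated from the data 0, 5, 3 and 3 of these were called. Those that held were adipocyte markers and textbook PPARγ targets in the PPARγ knockout and both high fat diet comparisons, textbook C/EBPα targets in both high fat diet comparisons, and fatty acid synthesis, lipolysis and ER stress genes in the PPARγ knockout. With an estimated correlation and without Pparg, the C/EBPα target list lost its call in both high fat diet comparisons. Its adjusted p was 0.0636 at 3 days and 0.0508 at 1 month.

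A core of 21 genes was called in all 4 knockout comparisons, each in the same direction throughout. The 8 that were higher were Angpt4, Cd33, Cdc6, Cdkn3, Cyp2f2, Itih4, Pcolce and Ralgds, and the 13 that were lower included Cebpa, Retn, the fatty acid receptor Ffar4, Pnpla3, the kinase Jak1, Ppp1r1a and Tmem120a; the genes outside the naming rule are named because they made up this overlap, after their values were seen. The core is limited by the chow calls (31.6% unchanged genes in simulated data). Of the 21 genes 16 stayed in it with precision weights, Angpt4, Cd33 and Ralgds not among them, and only 5, Cebpa, Retn, Ffar4, Tmem120a and 1700029I15Rik, stayed whichever array was left out, tests chosen after seeing the data. With 1 array left out 10 (without chow C/EBPα knockout replicate 3) to 22 genes were called in all 4. In the 3 C/EBPα comparisons 29 genes were shared, 10 higher and 19 lower. Both high fat diet comparisons shared 87 genes called higher, where independent lists would share 10.6, and 204 called lower against 18.7, with 1 gene called in opposite directions. The PPARγ knockout and the C/EBPα knockout at 1 month shared 320 genes called higher against 63.1 for independent lists, and 319 called lower against 57.7. Another 46 were called in opposite directions, against 121. On chow the C/EBPα and PPARγ knockouts shared 16 higher and 16 lower, against 3.63 and 3.65, with 2 in opposite directions against 7.28.

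**Figure D3:**
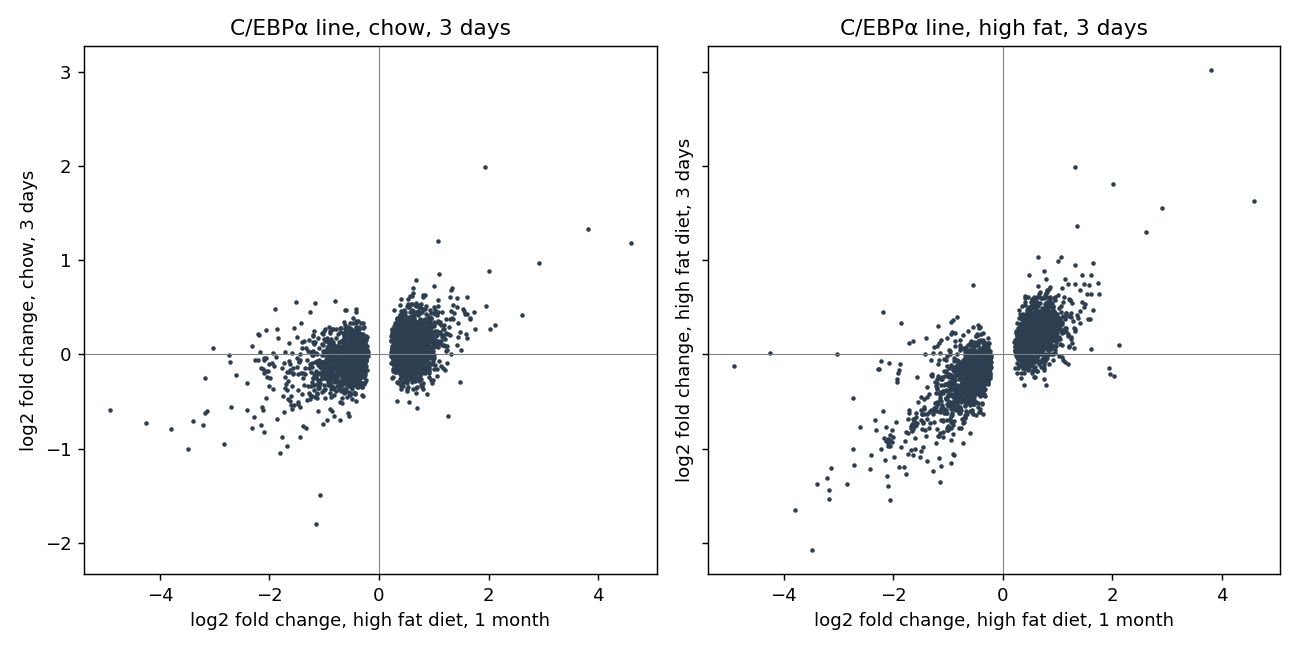
Log2 fold changes, knockout minus control, of the 2620 genes called at 1 month on high fat diet (horizontal axis) against those of the same genes in the C/EBPα knockout on chow or at 3 days on high fat diet (vertical axes), 1 point per gene. The slope of the points was 0.147 for chow and 0.368 for 3 days on high fat diet.

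Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.578 between 3 days and 1 month on high fat diet, 0.400 between PPARγ and C/EBPα at 1 month, 0.374 between PPARγ and C/EBPα at 3 days on high fat diet, 0.217 and 0.175 between C/EBPα on chow and the 1 month and 3 day high fat diet comparisons, and 0.121 between both factors on chow. The value of 0.175 was 0.116 without high fat diet knockout replicate 1, 0.264 without high fat diet knockout replicate 3 and 0.280 without background correction. No control array was shared between these comparisons.

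The effects of both knockouts on chow differed in 441 genes, 253 with a higher and 188 with a lower value in the C/EBPα knockout. Aldh3b2 was higher in the C/EBPα knockout and lower in the PPARγ knockout (log2 fold changes 0.83 against -1.40, difference 2.22 ± 0.21), and Celsr2, Acsm5, Nnat and Gpd1 had a lower value in the PPARγ knockout (differences 2.16 ± 0.27, 1.79 ± 0.25, 1.75 ± 0.37 and 1.66 ± 0.24). Angptl7, Adamtsl2, Mup3, Cyp4f14 and Mfsd2a had a higher value in the PPARγ knockout (differences -4.39 ± 0.42, -4.22 ± 0.43, -3.34 ± 0.32, -3.12 ± 0.28 and -2.63 ± 0.30). The difference of Adamtsl2 is of uncertain size as well, since 2 of its 3 PPARγ control arrays were at background. The count was 199 without PPARγ control replicate 2, 238 without PPARγ knockout replicate 2, 274 without PPARγ knockout replicate 3, 247 in a fit on these 12 arrays and 269 with covariates. Camera called 18 of 30 lists for this difference, and 0 with an estimated correlation (lowest adjusted p = 0.271).

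The effects of C/EBPα loss at 3 days on high fat diet and on chow were compared directly, and limma called 0 genes at an adjusted p under 0.05, while 1713 passed an unadjusted p of 0.05. The difference for Cebpa, lower in both, was -1.08 ± 0.20 (adjusted p = 0.0510). Without knockout replicate 2 on high fat diet the count was 24, without chow control replicates 1 and 2 it was 6 and 2, without chow knockout replicates 1, 2 and 3 it was 9, 2 and 10, without a filter or with a strict one it was 8 and 11, and without background correction it was 5 (Macroh2a1, Cebpa, Rassf8, Akap12 and Gnb5). The counts of 2 were Olfr516 and Hnrnph2, and H2-M11 and Taar4. These genes are named because the counts were small, after their values were seen. Camera called 8 of 30 lists, and 0 with an estimated correlation (lowest adjusted p = 0.301).

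Between 3 days and 1 month on high fat diet the effect of C/EBPα loss differed in 258 genes, 109 higher and 149 lower at 1 month. Angpt4, Mmd2, Retnlg, Hsd11b2 and Lcn2 had a higher value at 1 month (differences 2.97 ± 0.36, 2.26 ± 0.43, 2.16 ± 0.34, 2.02 ± 0.16 and 1.65 ± 0.31), and Serpina1b, Serpina1d, Crtac1, the Wnt antagonist Sfrp5 and Igfals a lower one (differences -4.78 ± 0.94, -4.26 ± 0.84, -3.04 ± 0.33, -2.63 ± 0.35 and -2.28 ± 0.25). The differences of Angpt4, Hsd11b2 and Serpina1d are of uncertain size. Their probes were above background in only 2 of 3 arrays of a 1 month group. Age, set and the Cebpa signal left (21.3% and 7.30%) differed with time in this comparison. The count was 145 without 3 day control replicate 1, 151 without 3 day knockout replicate 2, 168 without 1 month control replicate 1, 162 without 1 month knockout replicate 2 and 136 in a fit on these 12 arrays. Camera called 14 of 30 lists, and 0 with an estimated correlation (lowest adjusted p = 0.271).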

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

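The tests chosen only after the results were seen were those of slopes, of the Cebpa difference, of chance placement, the diets and the genes between for the chromosome 6 group, both tests of the Cebpa neighbours and the second probes; the tests of signal range and of other splits were chosen before. The effects of C/EBPα and PPARγ loss on chow, not separated from line and set, differed in 441 genes by a test of the difference. Among them Aldh3b2 differed by 2.22 ± 0.21, Celsr2 by 2.16 ± 0.27, Acsm5 by 1.79 ± 0.25, Nnat by 1.75 ± 0.37 and Gpd1 by 1.66 ± 0.24 (log2, C/EBPα minus PPARγ), and Angptl7 by -4.39 ± 0.42, Adamtsl2 by -4.22 ± 0.43, Mup3 by -3.34 ± 0.32, Cyp4f14 by -3.12 ± 0.28 and Mfsd2a by -2.63 ± 0.30. Other splits of the 12 arrays could not decide on chance, because a split that keeps a true grouping keeps that knockout effect. Of 100 drawn splits 6, the real one among them, gave as many genes, the highest other 1135. The other 5 each kept the true grouping of the PPARγ set, and among the 83 splits that kept neither the highest was 6.

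Between 1 month and 3 days on high fat diet the effect of C/EBPα loss differed in 258 genes by a test of the difference. Age and set differed as well. Angpt4 differed by 2.97 ± 0.36, Mmd2 by 2.26 ± 0.43, Retnlg by 2.16 ± 0.34, Hsd11b2 by 2.02 ± 0.16 and Lcn2 by 1.65 ± 0.31 (1 month minus 3 days), and Serpina1b by -4.78 ± 0.94, Serpina1d by -4.26 ± 0.84, Crtac1 by -3.04 ± 0.33, Sfrp5 by -2.63 ± 0.35 and Igfals by -2.28 ± 0.25. Those of Angpt4, Hsd11b2 and Serpina1d are of uncertain size, their probes being dim in a 1 month group. Other splits could not decide on chance, as above. Of 100 drawn splits 10, the real one among them, gave as many genes, the highest other 2372. The other 9 each kept the true grouping at 1 month. Among the 78 splits that kept neither grouping the highest was 3. For the difference between diets limma called 0 genes (1713 at an unadjusted p of 0.05), which any of the 100 splits must reach, so splits say nothing of chance there; the highest other gave 567. For each knockout comparison the 10 splits of 6 arrays are too few for a share under 0.05, with 1 split, the real one, as large: 158 genes against 32 at most in the others on chow, 1363 against 1 for PPARγ, 335 against 2 at 3 days and 2620 against 1 at 1 month on high fat diet. Splits that called many genes point to the structure of the samples. The 1135 and the 567 came from splits that kept both true groupings with 1 of them turned round, so that both knockout effects add up, and the 2372 from a split that kept only the grouping at 1 month.

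The effects of C/EBPα loss were smaller on chow than at 3 days on high fat diet across genes called at 1 month (slopes 0.147 and 0.368, ratio 0.401). A compressed signal range in the chow set is argued against by the ratio of SDs across genes, 1.00, and replicate noise in genes picked on the 3 day arrays by a ratio of slopes that stayed at or below 0.457 whichever array was left out. The genes called at 1 month respond on high fat diet, which may favour that diet. On the 1363 genes called in the PPARγ knockout on chow the slopes were 0.121 and 0.308. Their ratio stayed at or below 0.467, which argues against selection by diet. A slope also measures likeness to the profile used to pick the genes. PPARγ fold changes were closer to those of C/EBPα at 3 days on high fat diet than on chow (Pearson's r 0.374 against 0.121). These slopes thus do not separate a smaller effect on chow from a different one. The Cebpa probe kept 48.2% of its control signal on chow and 21.3% at 3 days on high fat diet. Its fold change on high fat diet minus that on chow was -1.08 ± 0.20 (adjusted p = 0.0510). Whether a lesser loss of Cebpa on chow made the other effects smaller stays open. Diet, array batch and the authors' normalization of each set cannot be told apart here, and no single gene passed the test of the difference. That the diet itself changes the size of the effect is therefore a hypothesis only.

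Rassf8, Sspn and Fgfr1op2, which lie close together on chromosome 6, fell by 1.27 on average (log2) in the C/EBPα knockout on chow, while their mean was -0.02 in the PPARγ knockout, -0.03 at 3 days and -0.31 at 1 month on high fat diet. A second Fgfr1op2 probe, above background in all 24 arrays, was at -0.44 on chow against -1.53, and with it the mean was -0.91. Chance placement of the 79 lower genes stays open: a share of 0.0387 of 100000 random draws held a group as tight, over groups of 2 to 6 genes, but the group was found by eye and 8 lists of called genes could have been searched. Loss of C/EBPα whatever the diet is argued against by the chow effect minus the mean high fat diet effect, -1.10 (SE 0.221), or -0.76 (SE 0.178) with the second probe, although the genes were picked on the chow arrays and none passed the test alone (adjusted p = 0.212 for Rassf8, 0.0510 for Sspn and 0.0607 for Fgfr1op2). A segment inherited with the knockout mice of that set might lower all 3 and stays open, since the segment and the group cannot be told apart; the genes between them, Itpr2 and Ints13, had a median of -0.0781. An effect of diet on these genes is a further open explanation that was not tested apart from the set.

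Cebpg and Chst8, near Cebpa on chromosome 7, had a mean log2 fold change of 0.57 on chow, 1.10 at 3 days and 1.48 at 1 month on high fat diet in the C/EBPα knockouts, and both were called higher on high fat diet. A second Cebpg probe, above background in all 24 arrays, moved less, at 0.34, 0.66 and 0.61 against 0.52, 1.37 and 1.36, and Pepd, which lies between both genes, was at -0.07, -0.27 and -0.19. Lower Cebpa mRNA by any route cannot be told from the PPARγ knockout and stays open. There Cebpa fell and the mean of both genes was -0.47 (SE 0.149), or -0.33 (SE 0.126) with the second probe, but Pepd fell as well (-0.96), so PPARγ loss may lower genes of this stretch apart from Cebpa. A constant difference inherited with the locus is argued against by the range of the 3 effects, 0.91 (SE 0.210). With the second probe the range was 0.63 (SE 0.179). This SE is that of a single fixed difference, and the genes were picked because they rose on high fat diet. Alone, neither gene passed the test of the difference between diets (adjusted p = 0.140 for Cebpg and 0.755 for Chst8). Nor did they between times (0.995 and 0.127). A consequence of the deletion at the locus itself remains a candidate explanation, and so do diet and time, none of which was tested. Kctd15, the next gene beyond Chst8, had -0.07, -0.72 and -1.46 in the same 3 comparisons and -0.03 in the PPARγ knockout.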

How the results depend on the processing

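The precision weights, the quantile normalization over all arrays, the covariates, the removal of a pair of arrays, the list tests on differences, those with 1 array left out or without Pparg and the tests of the core of 21 genes were chosen only after the results were seen. Of the named genes that were called, none changed its direction under the settings tried on them. Nor did a correlation, tried without background correction, without a filter and with 1 array left out, nor a called list under the settings tried on all arrays (background, filters, block, array weights and estimated correlation). With 1 array left out, 5 of 7 called lists lost their call at least once on chow, 2 of 18 for PPARγ, 7 of 15 at 3 days and 2 of 16 at 1 month on high fat diet, and 5, 2, 9 and 4 uncalled lists gained one. At 3 days on high fat diet the camera adjusted p of lymphocyte markers ranged from 3.8e-05 to 0.375, where the list turned to lower (without knockout replicate 3). That of skeletal muscle markers, lower without a call (0.425), ranged from 0.0116 to 0.603, with calls in both directions. The strict filter ended the list calls of red blood cell markers on chow (0.0513) and branched chain genes at 3 days on high fat diet (0.0662), and array weights that of lymphocyte markers there (0.169). Of 546 values of named genes, between 497 (replicate block) and 538 (no filter) kept their side of the threshold over the 7 settings that covered them all, and 520 of 529 did with the strict filter. Lost calls numbered 46 with the block, 24 of 141 with 2 arrays left out, and 24 and 20 of 139 without PPARγ control replicate 2 and knockout replicate 2. The slide as a block was not run, since no slide is known per array, the deposited series table became the source of all values, and 3 comparisons among controls were not tested. Median signal was 1.07 to 1.14 times background, which limits dim genes. For the changes below the cause was not tested, unless the setting itself tests fewer arrays or sets a stricter threshold.

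At an adjusted p under 0.01 the counts were 31 on chow, 604 for PPARγ, 147 and 1589 at 3 days and 1 month on high fat diet, and 116 and 93 for the differences between factors and between times. On chow, C/EBPα loss gave 322 genes without background correction, 267 probes when each was tested, 1 gene with only the arrays compared (Csrp1), 54 with array weights, 87 with quantile normalization over 24 arrays, 67 with precision weights and 85 with covariates. PPARγ loss gave 2073 with precision weights. At 3 days on high fat diet there were 77 with only the arrays compared, 599 with array weights and 118 with 2 arrays left out, and at 1 month 3964 probes were called. The difference between factors gave 247 with only those arrays and 269 with covariates, and that between times 136. The difference between diets, 0 under the other settings apart from leaving out 1 array, gave 5 without background correction, 8 without a filter and 11 with the strict one. Among 120 list tests 56 were called, 54 to 61 under other settings and 11 with an estimated correlation. Without Pparg the C/EBPα target list gained a call for PPARγ, and lost those with an estimated correlation at 3 days and 1 month. Without background correction Pearson's r was 0.285 for chow and 1 month, 0.280 for chow and 3 days on high fat diet, 0.469 for PPARγ and 1 month and 0.679 for both high fat diet times.

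With the replicate block the counts were 66 on chow, 222 at 3 days on high fat diet, and 211 and 167 for the differences between factors and times. The core of 21 genes called in all 4 comparisons was 16 with precision weights and 10 to 22 with 1 array left out. The replicate numbers share only a name: same-numbered arrays correlated at -0.26 to 0.09 in their deviations from the group means. Leaving out 1 array gave 670 to 1184 genes for PPARγ and 170 to 434 at 3 days on high fat diet. For the differences it gave 199 to 421 between factors, 0 to 24 between diets and 145 to 280 between times. Chow stayed within 109 to 144 and 1 month within 1836 to 2406. Pearson's r for chow and 3 days on high fat diet was 0.116 to 0.264.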

Other observations

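No further test was run for this part, and the genes and arrays in its last paragraph were chosen only after their values were seen. Adipogenic transcription factors moved both ways: of 20 tested, 3 rose and 6 fell at 1 month on high fat diet (5 and 6 adjusted over the list alone; camera adjusted p = 0.639), with Cebpg (1.36 ± 0.14), Ebf2 (0.53 ± 0.09) and Klf4 (0.48 ± 0.10) higher and Nr1h3, the liver X receptor (-0.65 ± 0.09), lower. In the PPARγ knockout 1 rose and 3 fell (3 and 5 adjusted over the list alone), with Srebf1 at -1.18 ± 0.15, and Cebpg was the called member at 3 days on high fat diet (1.37 ± 0.14). Of 20 fatty acid oxidation genes at 1 month, Acaa2 (0.75 ± 0.14) and Hadhb (0.79 ± 0.17) were higher and Acads (-0.40 ± 0.12) and Ehhadh (-0.66 ± 0.23) lower (2 and 2 adjusted over the list alone). Both lower ones lost their call when 1 array was left out (highest adjusted p = 0.168 and 0.216, without knockout replicate 2). Of the respiratory chain genes 3 of 27 rose at 1 month (3 adjusted over the list alone), each losing its call when 1 array was left out: Cox6c (adjusted p = 0.103 without control replicate 2), Atp5a1 (0.159 without control replicate 2) and Suclg1 (0.0879 without knockout replicate 3). ER stress genes went both ways at 1 month, 4 higher and 3 lower of 20 (4 and 3 adjusted over the list alone), with the chaperone Pdia4 at 0.38 ± 0.08 and Sesn2 at -0.71 ± 0.12.

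Cell death and p53 target genes were not called as a list in any comparison; in the PPARγ knockout 4 rose and 2 fell of 18 (4 and 3 adjusted over the list alone), with Trp53inp1 at 0.60 ± 0.12 and Phlda3 at -0.74 ± 0.12, and at 1 month Cdkn1a, a brake of the cell cycle, was at -0.71 ± 0.14. Circadian clock genes were not called as a list (at 1 month 0 of 13 higher and 1 lower, or 0 and 1 adjusted over the list alone; camera adjusted p = 0.536), and Nr1d1 fell at 1 month (-0.69 ± 0.15). Neutrophil markers were not called as a list (at 1 month 1 of 10 higher and 2 lower, or 1 and 2 adjusted over the list alone; camera adjusted p = 0.827). Retnlg rose at 1 month, while Elane (-0.52 ± 0.13) and S100a8 (-1.67 ± 0.47) fell, each losing its call when 1 array was left out (adjusted p = 0.0750 without control replicate 1 and 0.0631 without knockout replicate 1). Epithelial markers were not called as a list (at 1 month 1 of 13 higher and 1 lower, or 2 and 1 adjusted over the list alone; camera adjusted p = 0.806), and Trp63, a basal epithelial factor, was at least 2.08-fold lower at 1 month, its knockout arrays being at background. Skeletal muscle markers had medians of 0.03, -0.58, -0.33 and 0.24 on chow, in the PPARγ knockout, and at 3 days and 1 month on high fat diet, with no called member or list (at 1 month 0 of 16 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.645). At 3 days on high fat diet that list was called lower without control replicate 1 or knockout replicate 1 (camera adjusted p = 0.0116 and 0.0329) and higher without control replicate 3 (0.0181). Red blood cell markers were called higher on chow (median log2 fold change 0.24, camera adjusted p = 0.0453, adjusted p = 0.513 with an estimated correlation) and in the PPARγ knockout (median log2 fold change 0.35, camera adjusted p = 0.0170, adjusted p = 0.421 with an estimated correlation), where 1 of 6 rose (3 adjusted over the list alone). The call on chow ended without control replicate 2, knockout replicate 2 or knockout replicate 3 (camera adjusted p = 0.303, 0.202 and 0.103), and that in the PPARγ knockout without control replicate 1 or knockout replicate 3 (0.0854 and 0.115). In the nerve list S100b was the called member of 6 at 1 month (0.68 ± 0.10, above background in 2 of 3 control arrays; 1 higher adjusted over the list alone; camera adjusted p = 0.0779). In the sex-linked list the Y-linked Eif2s3y was higher at 1 month (0.76 ± 0.15; 1 of 4, 1 adjusted over the list alone), with no called list (camera adjusted p = 0.573). A list's median, mean and test differed in sign, without a call, for epithelial markers on chow and at both high fat diet times, for ER stress genes on chow, for lymphocyte markers in the PPARγ knockout and at 1 month, for brown fat genes at 3 days on high fat diet and for cell death genes at 1 month.

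Some values belonged to single arrays. Csrp1 read 5.45, 4.50 and 4.84 (log2) in the chow controls and 8.33, 7.88 and 8.16 in the knockouts, against 4.34 in 1 month knockout replicate 1 and 8.90 and 9.51 in the other 2. Hal, the histidine-degrading enzyme, read 7.51, 4.41 and 7.09 in the chow knockouts and 4.39, 4.28 and 4.36 in their controls. Serpina1b spread widely in the 1 month controls, at 11.1, 9.38 and 12.3. Relative to the mean of the controls, the muscle list stood at -1.98 in PPARγ knockout replicate 2.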
